A study of Danio rerio with 4 samples.

How the data were processed

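Gene counts of 4 libraries labelled as heart, 2 vehicle and 2 alfacalcidol by their titles, and 1 comparison table were used. Raw read counts for 31462 Ensembl genes per library were made by the authors with CASAVA, TopHat2 and featureCounts on GRCz10, per the submitters' processing notes; versions, strand setting and the handling of shared reads are not given in the sources used here. Reads shared between near-identical copies or overlapping genes are therefore uncertain. The log2 fold changes and log2 CPM levels of 14962 genes were deposited by the authors as the output of edgeR, per the submitters' processing notes. The p-values in the authors' deposited table come in an unadjusted and an adjusted column, and the adjusted column was checked to be the Benjamini-Hochberg adjustment of the other. The lowest log2 CPM in the authors' deposited table is -0.63; the filter behind it is not given in the sources used here. The numerator of its fold change is not given either and was read from the sign of cyp24a1, so each direction taken from it rests on that reading.

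Gene names came from the table for 14962 genes and from a table of gene names for 11551 more; 4949 had none. The table holds 109 symbols with more than 1 gene ID, which were not used for list matching. Coordinates are those of the authors' deposited table. No reference genome was used.

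Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr, group as the only term, two-sided), which left 22428 genes, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Intervals are 95% intervals from the quasi-likelihood standard error. The common dispersion was 0.0119, a biological coefficient of variation of 10.9%. Gene lists, 34 in all with 1396 of 1503 members matched, were tested with camera (limma 3.58.1, correlation 0.01), with camera at an estimated correlation and with fry, for lists of 5 or more members. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were RLE, upper-quartile or no scaling, no low-count filter, 1 CPM in 2 libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom, the replicate number as a block, an adjusted p of 0.1, a 2-fold minimum, each library left out and haemoglobin and mitochondrial genes left out. The crossed pairing with its list tests, the 2-fold minimum on the authors' deposited table and cameraPR on its p-values, at correlations of 0.01 and 0.05, were added after the data were seen, as were marker lists of other organs, globins and clock limbs.

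The naming rule took cyp24a1, vdra, vdrb and cyp27b1. It then took the 12 largest called changes in each direction at 1 CPM or more, with a gene symbol that is not a clone name and with both alfacalcidol libraries beyond both vehicle libraries. Last it took up to 4 called members per list by lowest p, or the 2 with the lowest p where none was called. The second part named no gene in the count libraries. It was applied to the authors' deposited table without its library criterion, which that table cannot meet. Pairs without a call are given for 7 lists and as a range for the others. Genes named for their level, such as actc1b, col2a1a and krt4, list members without a call in the table, and clock, immediate early and fasting genes beyond the rule's 4 were chosen after their values were seen.

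On simulated counts for the same 22428 genes and library sizes, with 50 genes changed at each fold and spread as in the 4 libraries, the quasi-likelihood test recovered 48% of genes at 1.5-fold, 76% at 2-fold, 82% at 4-fold and 100% at 16-fold, all with the right sign, with 16 false calls. With 1/10 of that spread, close to what some pairs of libraries show, it recovered 82%, 88%, 90% and 100% with 33 false calls. Its false calls thus exceeded the nominal 5% in both settings. The simulated libraries were drawn independently, whereas the real ones paired across the labels. These recoveries therefore do not give the power of the real fit. A simulated list of 53 genes gave a camera p of 0.757 with no shift and 1.29e-79 with a shift of 0.5 on the log2 scale, and cameraPR gave 0.755 and 1.38e-65. Depths were 31427486 to 39572163 counts per library. No pair of libraries was identical: over 19145 genes with 200 or more reads, the mean chi-square per gene was between 2.22 and 22.2 and the median between 0.827 and 2.37. Between 14.6% and 40.0% of these genes differed beyond counting error at an unadjusted p under 0.05.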

Results

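Per the labels, RNA of adult zebrafish hearts of the Ekkwill strain was compared after daily injection of vehicle or of alfacalcidol, a synthetic vitamin D analog that is hydroxylated in the liver to the active hormone. Injections ran over 3 days and hearts were taken 24 hours after the last, per the labels. The comparison asks which transcripts of the adult heart differ after exposure to a vitamin D receptor agonist. Each group had 2 libraries, and nothing in the labels says whether they came from separate animals or pools. A p-value from the counts therefore measures the spread between these libraries only. Totals were 31427486 and 34765941 counts for vehicle replicates 1 and 2, and 33957706 and 39572163 for alfacalcidol replicates 1 and 2. The series also holds the authors' deposited table of 1 comparison. It gives a log2 fold change, a mean level and p-values for 14962 genes and no values per library. It names no samples, so its contrast was read as alfacalcidol against vehicle from the series. Which libraries, and how many, stand behind its p-values is not known.

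The count libraries and the table did not describe the same RNA. The heart genes myl7, vmhcl and cmlc1, which encode cardiac myosin chains, stood at 20203, 43688 and 10133 CPM in the authors' deposited table. In the libraries labelled vehicle the same genes stood at 16.3 ± 0.477, 41.9 ± 1.78 and 9.48 ± 1.80 CPM (mean ± SD, n = 2). In those labelled alfacalcidol they stood at 16.1 ± 1.48, 43.8 ± 3.54 and 9.64 ± 0.0167 CPM (n = 2). The skeletal muscle actin gene actc1b ran the other way, at 8.75 CPM in the authors' deposited table and 15605 ± 893 CPM (SD, n = 2) in the libraries labelled vehicle. The cartilage collagen gene col2a1a was at 5836 ± 184 CPM (SD, n = 2) there, against 2.69 CPM in the authors' deposited table. Across 14952 genes the Spearman correlation of level between the count libraries and the authors' deposited table was 0.65. Pairs of the 4 libraries correlated between 0.994 and 0.998. Genes are not independent replicates in either value. The 2 sources are therefore reported apart, and the count libraries are called by their labels.

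**Figure D1:**
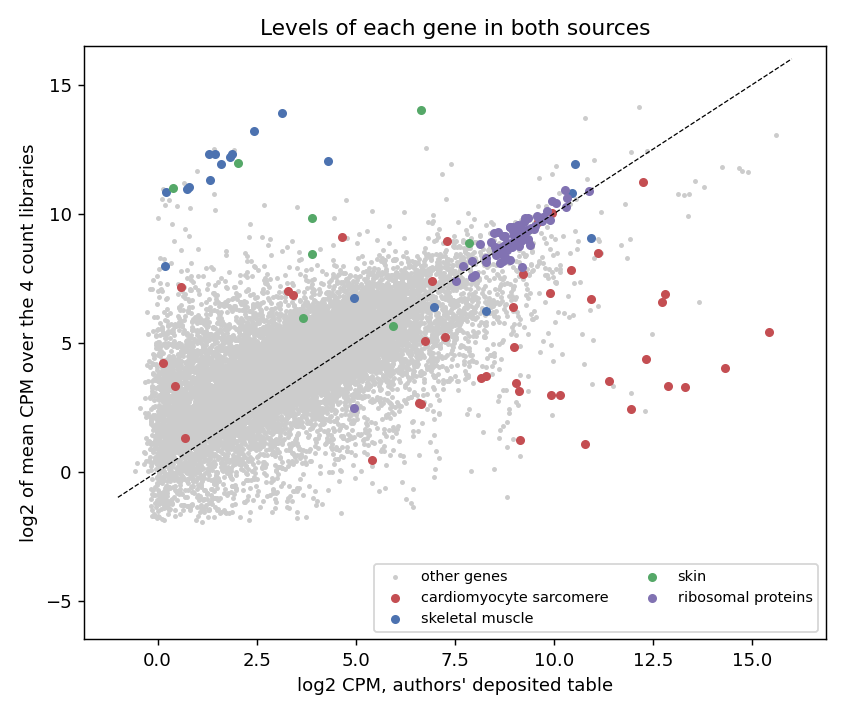
Level of each gene in log2 CPM in the authors' deposited table (x axis) and as the mean of the 4 count libraries (y axis), with 4 gene lists coloured and equal values dashed. Above the dashed line lie 43 of 77 ribosomal protein, 11 of 41 cardiomyocyte sarcomere, 16 of 19 skeletal muscle and 8 of 9 skin genes.

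In the authors' deposited table, 3006 of 14962 genes (20.1%) passed an adjusted p of 0.05 (Benjamini-Hochberg, from edgeR per the submitters' processing notes). Of these, 1627 had a positive and 1379 a negative log2 fold change. The counts of called list members below can be set against that 20.1%. The table does not name its numerator. Positive values are called higher here and read as higher with alfacalcidol, on the sign of cyp24a1, which encodes the 24-hydroxylase that degrades active vitamin D and is a known target of its receptor. The authors' deposited table lists cyp24a1 (chromosome 6, 55869049 to 55881711, GRCz10) at a log2 fold change of 1.53 with an adjusted p of 8.19e-05. Large changes were mostly increases: 192 genes were at least 8-fold higher and 11 at least 8-fold lower in the authors' deposited table.

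Of the 12 increases that the naming rule took from the authors' deposited table, 5 belong to the DNA replication or mitosis list, as do 33 of the 100 largest increases among all called genes. All 53 measured members of the DNA replication list were higher in the authors' deposited table, with a median log2 fold change of 2.65, and 53 passed when adjusted over the list alone. The helicase subunit genes mcm2, mcm3 and mcm4 were higher by 5.14, 5.36 and 4.80 on the log2 scale in the authors' deposited table (adjusted p 7.71e-105, 2.82e-93 and 8.84e-85), and tyms, which makes thymidylate, by 4.89. Of 65 mitosis genes, 63 were higher in the authors' deposited table, 63 when adjusted over the list alone, with a median of 3.44. Examples in the authors' deposited table are the mitotic kinase gene cdk1 at 4.33, the topoisomerase gene top2a at 4.06 and the condensin genes smc2 and smc4 at 3.87 and 4.06. The 2 members without a call, hmgb2a and ckap5, had log2 fold changes of -0.05 and -0.14 in the authors' deposited table. E2F1, encoding a transcription factor of the G1 to S transition, had the largest value of the authors' deposited table under the naming rule, 6.89 (adjusted p 5.12e-33; chromosome 23, 43575435 to 43594350). It was followed in the authors' deposited table by psmc3ip, dscc1, znf367 and dtl at 5.59, 5.54, 5.51 and 5.45. The rest were mcm3 and mcm2, given above, and mcm6, tk1, ube2t, haus5 and cdca7a between 5.22 and 5.09. Mean levels of these 12 genes in the authors' deposited table ran from 1.54 CPM for psmc3ip to 39.3 CPM for mcm6. E2F1, dtl and haus5 were at 1.91, 2.02 and 2.13 CPM, so the sizes of their changes are uncertain.

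**Figure D2:**
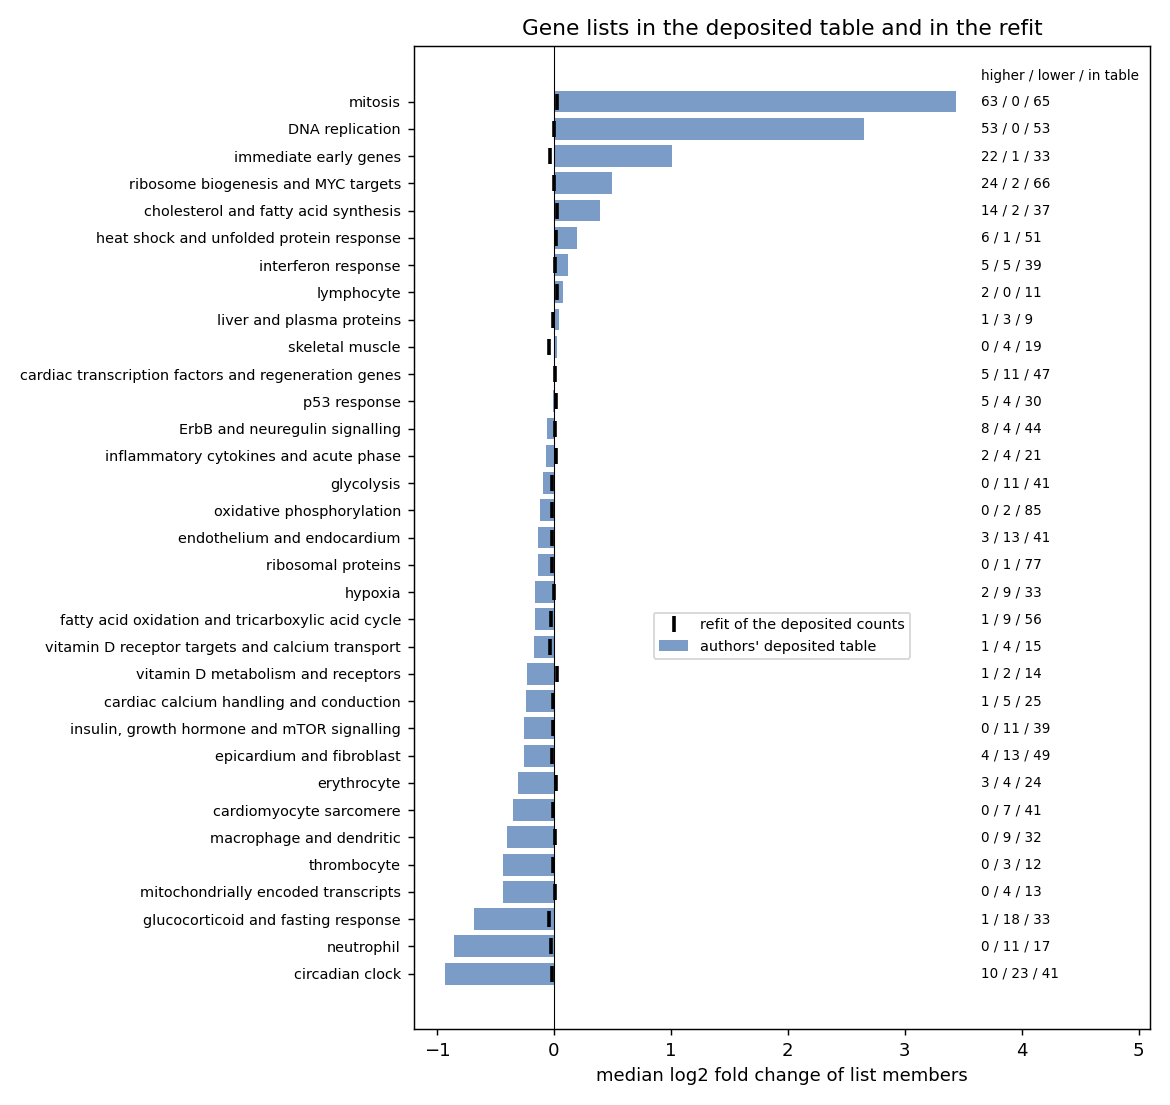
Median log2 fold change of the members of each gene list with 5 or more members in the authors' deposited table (bars) and in the refit of the count libraries (black ticks). Numbers at the right give members called higher, members called lower and members in the table; mitosis reaches a median of 3.44 in the authors' deposited table, and no refit median lies outside -0.04 to 0.09.

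Immediate early genes, which respond within minutes to stimulation, were also higher: 22 of 33 rose and 1 fell in the authors' deposited table, 23 when adjusted over the list alone, with a median of 1.01. They included egr1 at 3.998, fosb at 3.43, dusp2 at 2.47 and nr4a1 at 2.26 in the authors' deposited table, while klf4 was lower at -1.37. The ribosome biogenesis and MYC target list had 24 of 66 members higher and 2 lower in the authors' deposited table (33 adjusted over the list alone; median 0.49), among them mycb at 1.47 and heatr1 at 1.04. In the cholesterol and fatty acid synthesis list 14 of 37 members were higher and 2 lower in the authors' deposited table (17 adjusted over the list alone), with lss at 2.49, fads2 at 1.94 and pmvk at 1.57.

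Clock genes went both ways. Of 41 members of the circadian clock list, 23 were lower and 10 higher in the authors' deposited table (35 adjusted over the list alone; median -0.93). The genes per1b, bhlhe40, per1a and nr1d1, which encode repressors of the clock, were lower at -3.56, -3.46, -3.24 and -2.97 in the authors' deposited table. Also lower there were cry2 at -2.94, nfil3-6 at -3.13 and cipca at -3.08. Higher members in the authors' deposited table were rorcb at 2.703, nfil3-5 at 2.42 and clocka at 1.44. In the glucocorticoid and fasting response list 18 of 33 members were lower and 1 higher in the authors' deposited table (21 adjusted over the list alone; median -0.68), and 3 members, per1a, per1b and cry2, stand in both lists. Outside the clock, klf15 was lower at -2.07 and the pyruvate dehydrogenase kinase genes pdk2b and pdk2a at -2.96 and -1.55 in the authors' deposited table. The other large decreases that the naming rule took from the authors' deposited table were arg2 at -3.63, dhh at -3.54, the endothelial factor gene sox17 at -3.38 and zbtb46 at -2.98.

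Of 17 neutrophil genes 11 were lower and 0 higher in the authors' deposited table (13 adjusted over the list alone; median -0.85), with lyz at -2.43, mmp9 at -2.19 and npsn at -2.07. Of 32 macrophage and dendritic genes 9 were lower and 0 higher in the authors' deposited table (11 adjusted over the list alone), with cd74a at -0.67 and c1qc at -0.73. Of 41 cardiomyocyte sarcomere genes, 7 were lower and 0 higher in the authors' deposited table (14 adjusted over the list alone, median -0.35). That called share is below the 20.1% of all genes. The largest decreases were tcap at -2.14 and acta1a at -1.36, while myl7 stood at -0.45 with an edgeR adjusted p of 0.0501. For cardiac calcium handling and conduction 5 of 25 members were lower and 1 higher in the authors' deposited table (7 adjusted over the list alone), among them the natriuretic peptide genes nppa at -1.09 and nppb at -1.37. Among markers of other cardiac cell types in the authors' deposited table, 13 of 49 epicardium and fibroblast genes were lower, 4 higher and 32 not called. Of 41 endothelium and endocardium genes in the authors' deposited table, 13 were lower, 3 higher and 25 not called (20 and 17 of the 2 lists adjusted over the list alone). Examples in the authors' deposited table are myh11a at -1.36, cldn5a at -2.89 and tek at -1.11.

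Of 39 insulin, growth hormone and mTOR genes, 11 were lower and 0 higher in the authors' deposited table (11 adjusted over the list alone), with igfbp6b at -2.86 and socs2 at -1.69. For glycolysis 11 of 41 and for fatty acid oxidation 9 of 56 genes were lower in the authors' deposited table, against 0 and 1 higher (12 and 10 adjusted over the list alone). For mitochondrially encoded transcripts 4 of 13 and for hypoxia 9 of 33 genes were lower in the authors' deposited table, against 0 and 2 higher (10 and 13 adjusted over the list alone). Only 2 of 85 oxidative phosphorylation and 1 of 77 ribosomal protein genes were called in the authors' deposited table, all lower, and 0 and 0 passed when adjusted over the list alone. For ErbB and neuregulin signalling, 8 of 44 members were higher and 4 lower in the authors' deposited table (12 adjusted over the list alone), with the feedback inhibitor genes spry4 at 2.35, errfi1b at 1.46 and errfi1a at 0.995. The cardiac transcription factor and regeneration list had 5 of 47 members higher and 11 lower in the authors' deposited table (17 adjusted over the list alone), with tert at 2.201, cdk6 at 1.84 and ccnd2a at 1.72 against mmp13a at -1.99.

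For comparison with the short lists that follow, 20.1% of all genes were called in the authors' deposited table. Of 14 genes of vitamin D metabolism and receptors, 1 was higher and 2 lower in the authors' deposited table (3 adjusted over the list alone). The higher one was cyp24a1, whose sign set the reading of direction, so its own direction is not a result. The lower ones were cubn at -0.89 and gc, which encodes the vitamin D carrier protein of plasma, at -1.09. The receptor gene vdrb had a log2 fold change of -0.48 in the authors' deposited table with an adjusted p of 0.347; vdra was not matched by name, and cyp27b1 was not among the genes matched in the table. Of 15 receptor targets and calcium transport genes, 1 was higher and 4 lower in the authors' deposited table (7 adjusted over the list alone), with cdkn1a at 1.09 and g0s2 at -1.15. The remaining lists are given as members higher and lower. In the authors' deposited table they were 3 and 4 of 24 for erythrocyte, 2 and 0 of 11 for lymphocyte, 0 and 3 of 12 for thrombocyte, and 1 and 3 of 9 for liver and plasma proteins. Skeletal muscle had 0 and 4 of 19, interferon response 5 and 5 of 39, inflammatory cytokines 2 and 4 of 21, heat shock 6 and 1 of 51 and p53 response 5 and 4 of 30 in the authors' deposited table. The single gonad gene in the authors' deposited table, ccnb3, was higher at 2.60.

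As a test of whether each list stood apart from the other genes, cameraPR was run on the p-values of the authors' deposited table, a step chosen after its values were seen. At the preset correlation 20 of 33 lists passed an adjusted p of 0.05, 5 toward higher and 15 toward lower values, and at a correlation of 0.05 between genes 10 of the 20 passed. Those 10 include mitosis (cameraPR adjusted p 2.55e-175, and 5.93e-70 at the higher correlation) and DNA replication (4.74e-132 and 7.20e-57). They also include immediate early genes (cameraPR adjusted p 4.05e-11 and 7.95e-06), circadian clock (1.98e-09 and 0.000123), neutrophil (6.03e-07 and 0.000131) and cardiomyocyte sarcomere (2.39e-05 and 0.00857). Glucocorticoid and fasting response, ribosome biogenesis and MYC targets, macrophage and dendritic, and mitochondrially encoded transcripts complete the 10. The other 10 lists did not pass at the higher correlation. They were cholesterol and fatty acid synthesis and endothelium (cameraPR adjusted p 0.0692 each), insulin, growth hormone and mTOR (0.0743), and epicardium, fatty acid oxidation and thrombocyte (0.118 each). The last were cardiac calcium handling, glycolysis and hypoxia (cameraPR adjusted p 0.133 each) and ribosomal proteins (0.221). Neither vitamin D list passed at either correlation. At the preset one, metabolism and receptors had a cameraPR adjusted p of 0.440 and receptor targets one of 0.284. ErbB signalling (cameraPR adjusted p 0.673) and cardiac transcription factors (0.440) did not pass either. Nor did oxidative phosphorylation, liver, skeletal muscle, erythrocyte, heat shock, inflammatory cytokines, lymphocyte, interferon and p53 response. Because the table has no values per library, neither a left-out library nor a correlation between genes could be estimated for it.

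In the count libraries, no gene was called between the labels in the fit without a block. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 22428 genes. The smallest adjusted p of edgeR was 1.0, and 128 genes had an unadjusted p under 0.05, 70 higher and 58 lower. That is 0.571% of genes, where well-calibrated p-values without any difference would put a share of 0.05 below 0.05. The libraries paired across the labels, and that pairing enters the error of this fit. The 0 calls therefore do not show that no gene differs between the labels. With a block on the crossed pairing, vehicle 1 with alfacalcidol 2 and vehicle 2 with alfacalcidol 1, an alternative added after the data were seen, edgeR called 7 genes, 3 higher and 4 lower. Higher were zgc:158463 (log2 fold change 0.37), Metazoa_SRP (0.41) and CT027638.1 (0.24). Lower were histh1l (-0.22), arrdc3b (-0.25) and genes without a name (-0.50 and -0.80). The block was read from these same libraries, so its calls cannot be assigned to the treatment. With that block 4 lists passed by camera at the preset correlation: skeletal muscle (adjusted p 0.00460), glucocorticoid and fasting response and glycolysis (0.0202 each) toward lower and cholesterol and fatty acid synthesis (0.0202) toward higher values. None passed with that block by camera at an estimated correlation (smallest adjusted p 0.965) or by fry (0.656). The exact test of edgeR, limma-voom and DESeq2 also called 0, with 133, 121 and 20 genes at an unadjusted p under 0.05. The gene cyp24a1 stood at 3.50 and 9.70 CPM in the libraries labelled vehicle and at 6.80 and 3.07 CPM in those labelled alfacalcidol (log2 fold change -0.43, 95% interval -1.67 to 0.80, edgeR adjusted p 1.0). Within both crossed pairs cyp24a1 was lower under the alfacalcidol label, at 3.07 against 3.50 and 6.80 against 9.70 CPM. The receptor gene vdrb had a log2 fold change of -0.01 (interval -0.81 to 0.79). CYP27B1, encoding the enzyme that activates vitamin D, had one of 0.06 (interval -0.42 to 0.55). The proliferation gene mcm2 was at 98.4 ± 9.39 CPM (SD, n = 2) in the libraries labelled vehicle and 98.6 ± 7.72 CPM (n = 2) in those labelled alfacalcidol.

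**Figure D3:**
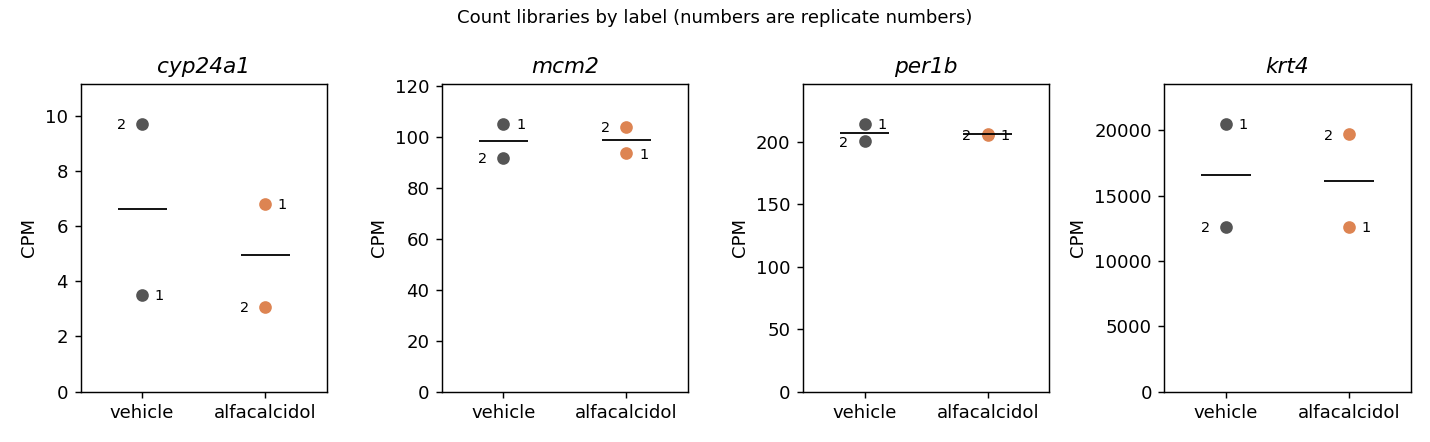
CPM of cyp24a1, mcm2, per1b and krt4 in each count library by label, with replicate numbers beside the points and the mean of 2 as a bar. For cyp24a1, mcm2 and krt4 the libraries within each label differ more than the means do; krt4 lies at 20498 and 12629 CPM for vehicle replicates 1 and 2 and at 12562 and 19746 CPM for alfacalcidol replicates 1 and 2.

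Without a block, none of the 34 lists passed in the count libraries by camera at the preset correlation (smallest adjusted p 0.385), by camera with an estimated correlation (smallest adjusted p 0.957) or when adjusted over the list alone, where 0 members passed in any list. List medians ran from -0.04 to 0.09. For DNA replication the members with the lowest p were tyms at a log2 fold change of 0.19 ± 0.09 (SE) and ccne1 at -0.24 ± 0.15. For mitosis the pair was ccnb3 at 0.19 and melk at 0.19, for the clock nr1d4b at -0.16 and cry1bb at -0.10, and for immediate early genes fosab at -0.19 and klf2a at -0.17. For vitamin D metabolism it was cyp27a1.4 at 0.54 and rxrgb at -0.18, for the sarcomere cryabb at 0.30 and tnnc1b at -0.08, and for skeletal muscle eno3 at -0.06 and ckma at -0.06; over all lists such pairs ran from -0.69 to 1.42. Leaving out 1 library at a time, between 5 and 7 lists passed by camera, some in opposite directions depending on the library. Oxidative phosphorylation had a median of -0.11 without vehicle replicate 1, -0.14 without alfacalcidol replicate 1, 0.07 without vehicle replicate 2 and 0.10 without alfacalcidol replicate 2.

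Of the 3006 genes called in the authors' deposited table, 2953 were tested in the count libraries and 0 were called there. Over 14777 shared genes the log2 fold changes of the authors' deposited table and the refit had a Pearson correlation of 0.018 and a Spearman correlation of 0.0479; genes are not independent replicates. Of the called genes 53.5% had the same sign in both. At 2-fold or more the authors' deposited table calls 1233 tested genes, and for 1217 the 95% interval of the refit excluded its value. The 2 sources therefore differed beyond the spread of the count libraries. These intervals do not give the reason.

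**Figure D4:**
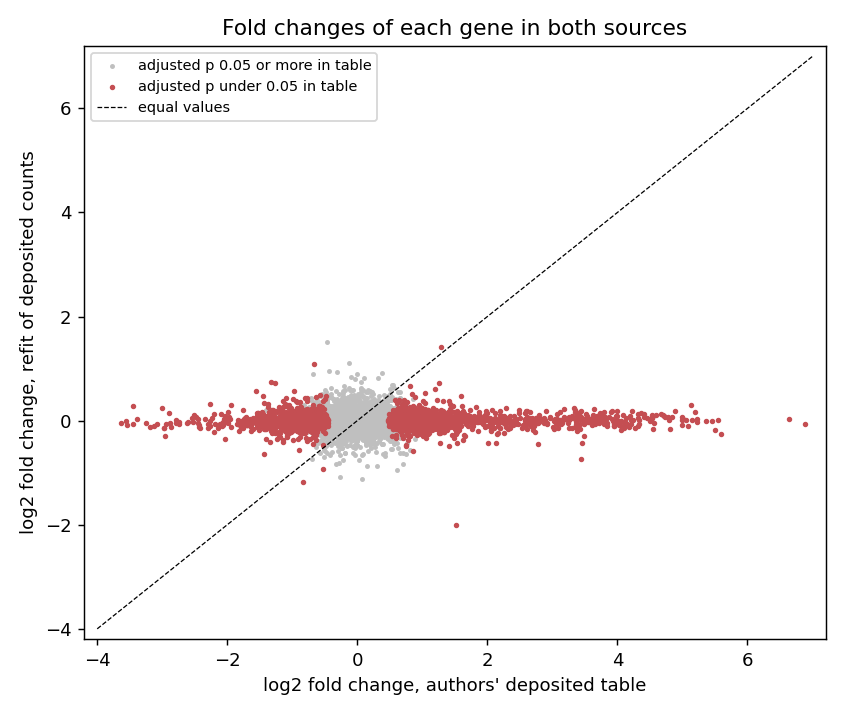
Log2 fold change of each shared gene in the authors' deposited table (x axis) against the refit of the count libraries (y axis), with genes called in the table in red and equal values dashed. Called genes run from -3.63 to 6.89 along the x axis of the authors' deposited table. On the y axis they do not follow the dashed line (slope 0.00257 over called genes), though single ones such as stat1b lie as far from 0 as 1.42. The Pearson correlation is 0.018 over 14777 genes.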

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

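The crossed pairing with its list tests, the 2-fold minimum on the authors' deposited table and cameraPR were chosen after the results were seen. The count of 0 changed genes in the count libraries held under 16 alternatives: the scalings, filters, tests and thresholds, the omission of haemoglobin and mitochondrial genes, and each left-out library (0 to 0). A left-out library leaves 1 in its group, which is assumed to vary as the other group does. Most of these fits take their error from libraries of the same label, so the pairing across labels counts as error. The common dispersion was 0.0119 for the labelled split and 0.00122 for vehicle 1 with alfacalcidol 2 against vehicle 2 with alfacalcidol 1. A 2-fold minimum cannot add calls. The repeated 0 therefore does not show that no gene differs between the labels. With the replicate number as a block the fit called 0 genes and 0 lists; replicates of the same number deviated in opposite directions (r = -0.46 across genes). With the crossed pairing as the block, vehicle 1 with alfacalcidol 2 and vehicle 2 with alfacalcidol 1, 7 genes and, by camera at the preset correlation, 4 lists were called, but 0 lists by camera at an estimated correlation or by fry. The number of lists passing, 0 in the main fit, was 5 to 7 when a library was left out. The 3006 calls of the authors' deposited table became 3795 at an adjusted p of 0.1 and 1262 with a 2-fold minimum, the latter by its own construction.

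With 1 library left out, 5 list medians were called with a sign opposite to the main fit. Their ranges over the 4 left-out libraries were -0.143 to 0.097 for oxidative phosphorylation, -0.174 to 0.0944 for glycolysis and -0.109 to 0.0828 for fatty acid oxidation. They were -0.121 to 0.130 for erythrocyte and -0.102 to 0.135 for mitochondrially encoded transcripts. By construction such a fit sets 1 library against 2 that differ from each other. Of the other values for single genes and lists, 959 kept their direction and side of the threshold, 84 without a call changed sign or moved, and 21 passed the threshold in the same direction. The sign of cyp24a1 in the count libraries turned without vehicle replicate 2 (0.49) and without alfacalcidol replicate 2 (0.03).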

Other observations

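Tests of dilution, of organ markers, of exchanged labels and both tests on clock genes were chosen after results they bear on, or some of the genes in them, had been seen. The tests of identifiers, globins and depth were fixed before their own results were seen. Marker lists of organs outside the heart describe what the count libraries held. Of the markers matched, 15 of 17 eye, 14 of 16 brain and nerve, 14 of 15 cartilage and bone, 23 of 23 skin, 5 of 15 exocrine pancreas, 7 of 16 intestine and 1 of 7 hatching gland genes were at 10 CPM or more in all 4 libraries. The authors' deposited table had 0, 1, 3, 7, 1, 1 and 2 of them at that level. The 1 hatching gland gene was xbp1, which was at 148 CPM in the authors' deposited table. The hatching gland gene he1.1 was at 19.5 and 17.9 CPM in vehicle 1 and alfacalcidol 2. In vehicle 2 and alfacalcidol 1 he1.1 was at 1.04 and 0.236 CPM, while klf17 ranged only from 4.42 to 5.98 CPM over the 4 libraries. The ultraviolet opsin gene opn1sw1 was at 1340 ± 384 CPM (SD, n = 2) in the libraries labelled vehicle and 1262 ± 407 CPM (n = 2) in those labelled alfacalcidol. The embryonic globin gene hbae3 was at 661 ± 155 CPM (SD, n = 2) and 644 ± 155 CPM (n = 2), while the adult globin gene hbaa1, at 69.9 CPM in the authors' deposited table, was at 0.148 ± 0.0749 CPM and 0.0926 ± 0.0477 CPM.

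The count libraries were unlike the heart profile of the authors' deposited table, and gene identifiers out of register are argued against as the reason, since the ribosomal protein list had a median above 100% of 10000 random lists. Heart RNA diluted by other tissue stays open: over 15 sarcomere genes at 1000 CPM or more in the authors' deposited table, the count libraries held 0.0800% to 49.3% of that level, with a median of 0.423%. The highest ratio was that of ttn.2, at 2392 CPM over the 4 libraries against 4848 CPM. The cardiac myosin genes myl7, vmhcl and cmlc1 were at 16.2, 42.9 and 9.56 CPM against 20203, 43688 and 10133 CPM. The lowest ratio limits RNA of the table's profile to a very small share and does not exclude it. The rule of this test was rewritten after its values were seen. Only a sarcomere gene without reads would have excluded dilution under it, so its outcome was known and decides nothing. Embryonic or larval specimens are a candidate explanation, as embryonic and larval genes gave at least 99.96% of alpha globin reads in each library, although the labels name adult heart. RNA of whole animals, or files of another experiment, stays open: of the 5 organ lists set for this test, which left out intestine and, at 14.3%, hatching gland, the lowest was exocrine pancreas with 33.3% of its markers at 10 CPM in all 4 libraries, between the 20% and 50% that would have decided it.

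The 4 libraries also paired across their labels: of the 3 ways to split them 2 against 2, the labelled one called 0 genes, replicate 1 against replicate 2 called 0, and vehicle 1 with alfacalcidol 2 against the other two called 3818, which points to a structure of the samples that the labels do not give. Depth is argued against, since 3308 genes were called in that split after thinning to equal totals. An exchange of labels between the groups would also pair libraries across them and stays open. The largest absolute Spearman correlation with the authors' deposited table over the 3 splits was 0.0479, which decides nothing because the 2 sources differ in RNA. What the structure is was not tested, and it cannot be assigned to a treatment.

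Clock genes differed in the authors' deposited table: 4 of 6 activator genes were higher and 0 lower, and 17 of 17 genes picked as repressor and output limb were lower. That pick leaves out list members that were not lower, such as nfil3-5 at 2.42, and several of the 17 had been seen among the largest decreases before it was made. Called clock list members lay on both sides in the authors' deposited table, 23 lower and 10 higher. A shift of all transcripts in 1 direction alone would not give this. The rule for this test was written after those counts were seen, so its outcome was known in advance. The other 35 members of the clock list had 6 higher and 23 lower in the authors' deposited table. Against them the activator genes gave p = 0.00513 (two-sided Fisher's exact test on called members), a split chosen after the values were seen. Clock genes are not independent replicates, so this p-value describes the counts only. Collection of the 2 groups at another phase of the daily cycle and an effect of alfacalcidol on the clock would give the same counts and cannot be told apart here, because collection times are not given in the sources used here.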
